A study of Mus musculus with 30 samples.

How the data were processed

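The deposited tables held TPM per gene, computed by the authors. Per the submitters' processing notes the reads were handled with HISAT2, StringTie, featureCounts and DESeq2 against mm10, with no versions and no statement of which tool gave the TPM. Per the labels' protocols total RNA was taken and cDNA was made and amplified with a kit for single cells and low input. The labels and the column names placed all 30 columns in 10 groups, 0 columns were left unmapped, and no group was inferred from the values. How reads shared by near-identical genes were assigned, the read depth and any steps before the TPM are not given in the sources used here.

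All settings of the planned analysis, its alternatives and the gene lists were fixed before the data were examined. TPM were taken as log2(TPM + 1) and fitted in R 4.3.3 with limma 3.58.1, as a mean per group over all 30 libraries, with a weight for each table (arrayWeights), a trend of variance on abundance and robust moderation, on 20 residual degrees of freedom. The fit held 13225 genes with at least 1 TPM in at least 3 libraries, and each comparison tested those that met this in its own libraries. Adjusted p is limma's moderated t test with the Benjamini and Hochberg adjustment within a comparison, and a gene was called at 0.05. Weights came out at 2.39 for KOiMOS MPP3, 0.512 and 0.799 for WTiMOS MPP3 of 3 and 24 months, and 0.997 and 1.03 for WTiMOS MPP4. Comparisons of age and of cell type averaged T1 and T2, and differences of the T2 and T1 step were interaction contrasts of the same fit.

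The 26 gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, where at least 5 members were tested. The list of mitochondrially encoded genes had 0 members in the tables and was not tested. Counts of list members use the calls of the whole comparison, and the counts adjusted over the list alone use an adjustment within the list. Genes named in the text followed a rule: Bcl11a always, up to 12 higher and 12 lower genes by size of change among called genes with no overlap of libraries and a mean of at least 5 TPM in the higher group, up to 4 members of each list by smallest p, and up to 6 genes of smallest adjusted p for each difference of differences. Predicted genes and pseudogenes were left out of the rule, and Y-linked genes and Xist were given by library in every table. Positions came from GENCODE vM21 on GRCm38, where 23376 of the listed symbols (95.7%) had an entry.

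Settings varied as planned were a pseudocount of 0.1, no filter, median-ratio rescaling, a fit of only the groups compared without weights, replicate number as a block, each library left out in turn, and the estimated correlation for lists. Rescaling divided each library by the median ratio to the geometric mean of genes above 1 TPM in all libraries. Added after the data were seen were the removal of a trend on GC content and transcript length from every library, the omission of X and Y linked genes, and a spread for each table alone. Comparisons of age and of cell type were also read within T1 and within T2 cells, as contrasts of the planned fit added after the data were seen. The spread for each table alone fitted each table by itself and combined tables with Satterthwaite degrees of freedom.

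Simulated data with 200 genes changed by log2 0.5, 1 or 2 showed that the planned fit makes too many false calls where a gene's spread differs between tables. When each table was given its own measured spread, 21.2% to 33.9% of the calls of T2 against T1 were false with the planned fit and 3.63% to 8.57% with the spread of each table alone. A second simulation, with each table's spread shrunken, gave 16.6% to 27.3% and 3.85% to 9.26%. A later simulation, made after these, gave each gene a single spread in all tables, which the planned fit assumes, and 1.71% to 10.3% of its calls were then false. For the KOiMOS and WTiMOS difference of differences the shares with shrunken spreads were 28.1% planned and 13.3% with the spread of each table alone, and for KOiMOS against WTiMOS in T2 cells 19.6% and 6.45%. A simulated difference of differences had at first imposed means below 0, and this was corrected. The planned fit was kept, because its settings were fixed, and the alternative stands beside it.

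With shrunken spreads the planned fit recovered 43.3% to 88.1% of the genes changed by log2 0.5 between T2 and T1, 86.6% to 100% of those changed by 1 and 98.5% to 100% of those changed by 2. In the simulated list test the 1 list shifted by log2 0.5 was called and 0 others were. A simulated trend on GC content made 95.7% of calls false in 24-month MPP4, and 17.3% after the correction.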

Results

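RNA was sequenced from multipotent progenitors of mouse bone marrow, the cells that stand between blood stem cells and the committed lineages. MPP3, a subset known for its myeloid output, and MPP4, a subset known for its lymphoid output, were sorted by flow cytometry from mice labelled KOiMOS or WTiMOS. Libraries were made of T1 and of T2 cells, which the labels name without saying which cells carry which state of Bcl11a or whether both came from the same animals. The 30 libraries formed 10 groups of 3, in 5 tables that each held a T1 and a T2 group: KOiMOS MPP3 at 3 months, WTiMOS MPP3 at 3 and at 24 months, and WTiMOS MPP4 at 3 and at 24 months. KOiMOS MPP3 at 24 months, which the series design names, was not analysed here. Nothing in the labels says whether replicates came from separate animals, so p-values measured only the spread between these libraries, which may be technical.

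Values were TPM (transcripts scaled to a common total), and every library summed to 1e+06, so the sequencing depth was unknown. Between 10519 and 12008 genes reached 1 TPM in a library, and libraries of a group correlated with Pearson's r of 0.977 to 0.996 across genes. The largest axis of variation, 68.5% of the variance, separated the KOiMOS and WTiMOS MPP3 libraries of 3 months from those of the other 3 tables. Globins, tryptases, Wfdc17, Mrgpra2a and Mrgpra2b, and ribosomal proteins have near-identical copies, and their values are uncertain because the handling of shared reads is not given in the sources used here. Fold and log2 changes are on the log2(TPM + 1) scale, which understates the change of genes near 0. Groups are given as mean ± SD, with n = 3 for T1 or T2 cells of a table and n = 6 where both were pooled. A pair of values gives T2 against T1, 24 against 3 months, MPP4 against MPP3 or KOiMOS against WTiMOS, in that order.

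**Figure D1:**
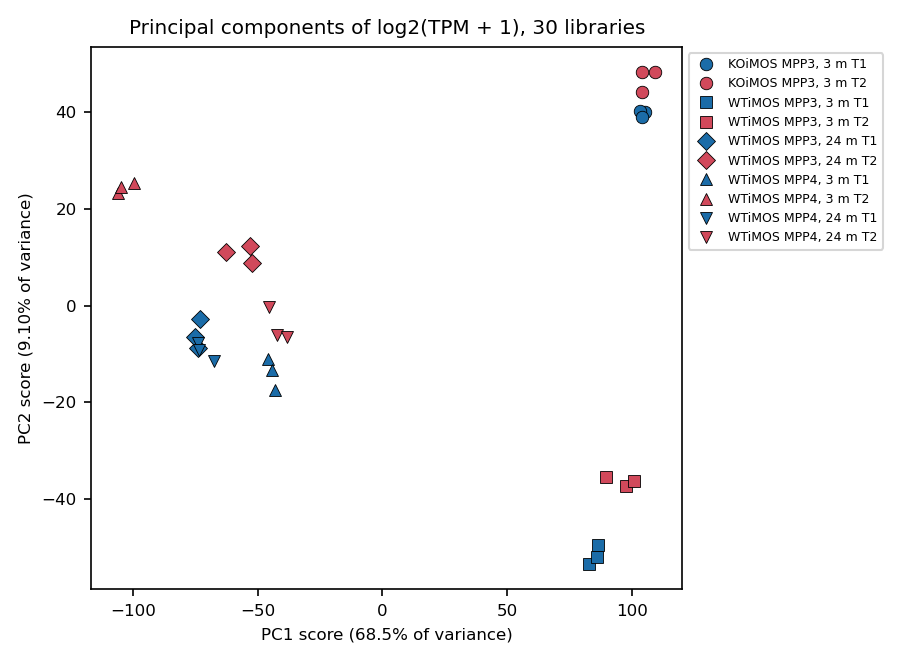
Scores of the 30 libraries on the 2 leading principal components of log2(TPM + 1), with the percent of variance on each axis and each point a library shaped by table and coloured by T1 or T2. The first component, with 68.5% of the variance, sets the KOiMOS and WTiMOS MPP3 tables of 3 months apart from the other 3 tables, and the second holds 9.10%.

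Bcl11a, a zinc finger repressor of transcription known for its part in lymphoid development and globin switching, is the gene the study is about (chromosome 11, positions 24078056 to 24174123, plus strand, protein coding, GRCm38). It was higher in T2 than in T1 cells in all 4 WTiMOS tables. In MPP3 it was 78.5 ± 6.06 TPM in T2 and 45.2 ± 2.79 in T1 at 3 months (log2 0.78, adjusted p = 0.000543), and 39.1 ± 5.63 and 11.2 ± 2.32 at 24 months (log2 1.73, adjusted p = 2.69e-12). MPP4 gave 65 ± 1.2 TPM in T2 and 39.4 ± 3.83 in T1 at 3 months (log2 0.71, adjusted p = 1.01e-06), and 66.7 ± 4.23 and 25.1 ± 2.09 at 24 months (log2 1.37, adjusted p = 3.97e-11). With median-ratio rescaling the MPP4 steps were log2 1.61 at 3 and 0.96 at 24 months, so which age had the larger step depended on the scaling. The libraries labelled KOiMOS held 68.2 ± 3.41 TPM in T2 and 70.3 ± 2.48 in T1, a difference that did not pass the test (log2 -0.04, adjusted p = 0.661). A loss of Bcl11a RNA was not seen in either KOiMOS group, and gene-level TPM would not show a deletion that leaves most of the transcript in place.

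RNA of the Y chromosome was absent or nearly absent in T1 cells of 3 tables. The sum of Eif2s3y, Ddx3y, Kdm5d and Uty was listed at 0 in T1 of 24-month MPP3 and of 3-month MPP4 and averaged 0.106 TPM in T1 of 24-month MPP4, where T2 held 63.4, 111 and 162 TPM. Xist, expressed from the inactive X chromosome of females, averaged 69.2, 97.0 and 67.9 TPM in those T1 groups and 20.4, 22.8 and 29.3 in T2. Both cell types of the 3-month MPP3 tables held Y-linked RNA, more in T1 than in T2, with 111 ± 1.96 against 57.2 ± 3.39 TPM in KOiMOS and 73.2 ± 7.94 against 43.6 ± 13.2 in WTiMOS. Xist averaged 21.8 in T1 and 28.9 in T2 of KOiMOS, and 30.02 and 37.0 of WTiMOS. T1 and T2 cells of every table thus differed in mean sex-linked RNA as well as in the label, and every change given for them holds with that difference present.

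**Figure D2:**
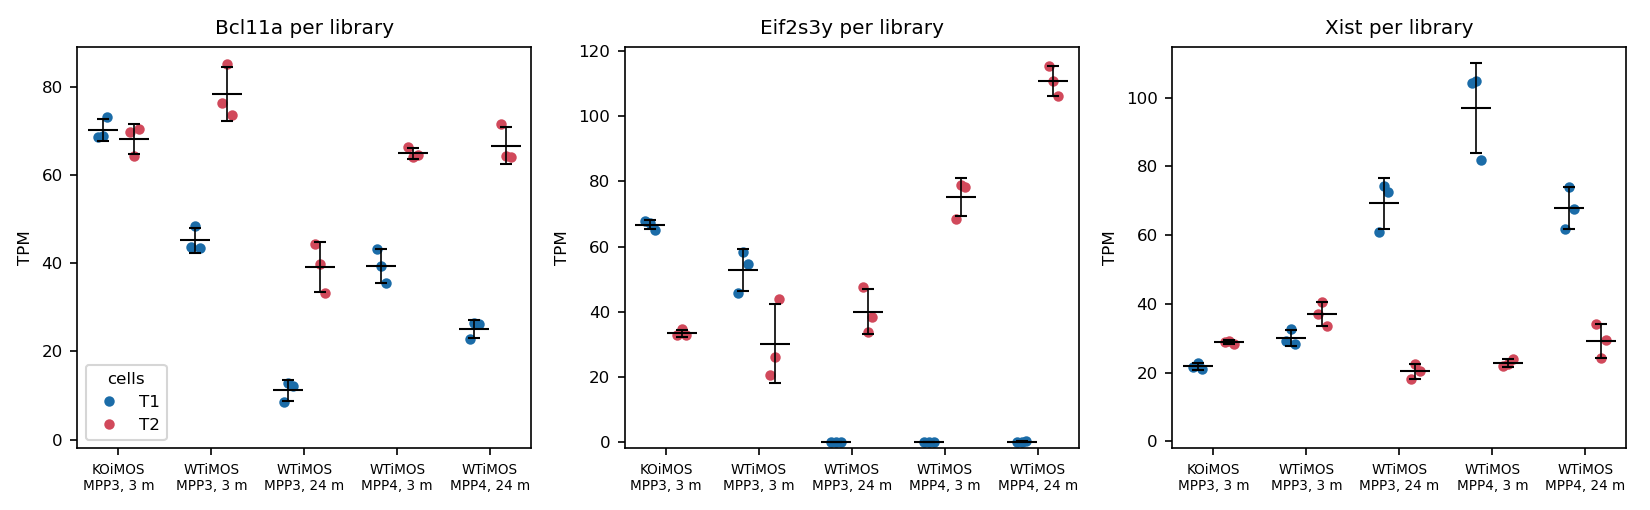
TPM of Bcl11a, Eif2s3y and Xist in each of the 30 libraries, by table and T1 or T2, with a line at the mean and bars of 1 SD (n = 3). Bcl11a lies higher in T2 in the 4 WTiMOS tables and near 70 TPM in both KOiMOS groups, and Eif2s3y is at or near 0 in T1 of 24-month MPP3 and both MPP4 tables.

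Whether T1 and T2 cells of KOiMOS mice differed at 3 months was asked in MPP3. T2 cells held much more RNA of mast cells and red cells. Among mast cell proteases Tpsb2 rose (1860.4 ± 70.6 against 62.2 ± 5.76 TPM, 29.5-fold), as did Mcpt4 (491 ± 30.5 against 17.4 ± 3.98, 27.1-fold) and Cma1 (1075 ± 39.4 against 44.5 ± 17.3, 24.7-fold). The beta globin Hbb-b2 was 17-fold higher (1246 ± 32.6 against 74.3 ± 19.3). Klf1, a transcription factor of red cell genes, was 4.89-fold higher (21 ± 1.23 against 3.55 ± 0.859). Id2, an inhibitor of E proteins, was 6.21-fold higher (53.9 ± 1.83 against 7.89 ± 1.25). Paqr5, a progestin receptor, was 1.7 ± 0.218 TPM in T2 and 30.2 ± 1.66 in T1 (log2 -3.53). The chemokines Ccl3 and Ccl4 fell by 2.80 and 2.72 on the log2 scale. Eif2s3y, on the Y chromosome, was 33.4 ± 1.07 TPM in T2 and 66.7 ± 1.4 in T1.

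Of 30 proliferation genes 27 were higher and 1 lower in T2 cells (adjusted over the list alone, also 27 and 1; adjusted p = 6.84e-23, and adjusted p = 0.000112 with an estimated correlation). Birc5, a mitotic regulator, was 179 ± 9.31 against 93.8 ± 7.3 TPM. Basophil, mast cell and eosinophil genes rose, with 14 of 19 higher, none lower and 5 not passing (15 and 0 adjusted over the list alone). Cpa3 was 974 ± 68.9 against 247 ± 11.6 TPM, and the list had adjusted p = 1.39e-15, and adjusted p = 0.000345 with an estimated correlation. Erythroid genes did likewise, with 19 of 22 higher and none lower (19 and 0 adjusted over the list alone). Car2, a carbonic anhydrase, was 1971 ± 95.6 against 796 ± 23.6, with adjusted p = 1.19e-14 of the list, and adjusted p = 0.000345 with an estimated correlation. Neutrophil and monocyte primed genes were higher in 14 and lower in 4 of 25 (the same counts adjusted over the list alone, adjusted p = 3.99e-05, and adjusted p = 0.0356 with an estimated correlation). Mpo, the myeloperoxidase of granules, was 5125 ± 43 against 2454 ± 94.1 TPM, and Ms4a3 was 236 ± 19.9 against 88.4 ± 3.28.

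Lymphoid primed genes fell in T2 cells of KOiMOS MPP3, with 11 lower and 3 higher of 19 (the same adjusted over the list alone). Flt3, a cytokine receptor of lymphoid priming, was 68.9 ± 5.55 against 116 ± 2.28 TPM (adjusted p of the list = 0.00118, and adjusted p = 0.0356 with an estimated correlation). Genes of NF-kappa-B and inflammation were lower in 13 and higher in 4 of 25 (13 and 5 adjusted over the list alone, adjusted p = 0.0112, and adjusted p = 0.0363 with an estimated correlation). B cell genes were lower in 8 and higher in 1 of 10 (also adjusted over the list alone, adjusted p = 0.000252), a call lost at adjusted p = 0.0956 with an estimated correlation. Vpreb1, part of the surrogate light chain, was 3.29 ± 1.03 against 10.4 ± 1.61 TPM, and Cd79b was 56.3 ± 0.454 against 75.9 ± 0.723. The stem cell and quiescence list did not pass (5 higher, 9 lower and 9 not passing of 23, 6 and 11 adjusted over the list alone). Ly6a, the surface antigen Sca-1, was 64.7 ± 4.34 against 137 ± 3.75 TPM. Nor did the stromal and endothelial list, with none higher, 1 lower and 4 not passing of 5 (1 and 2 adjusted over the list alone).

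In limma's test 4417 of 12100 genes differed between T2 and T1 cells of KOiMOS MPP3, 1890 higher and 2527 lower, and 436 of them by at least 2-fold. The balance turned to 2328 higher and 2182 lower after median-ratio rescaling. With the spread of this table alone 3888 of the 4417 were called in the same direction. In simulated data, given with the processing, 33.2% of the calls of this comparison were false when each table had its own measured spread, and 27.3% with those spreads shrunken. Over all T2 and T1 comparisons the shares were 21.2% to 33.9% and 16.6% to 27.3%. The simulated data changed 200 genes, far fewer than the 4417 called here, so these shares are not those of the real calls. Of the named genes only Prss34 lost its call with the spread of each table alone, which their choice by large change or small p in the same libraries favours.

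The same question in WTiMOS MPP3 of 3 months gave changes of lineage genes. T2 cells held more RNA of stem and red cell regulators. Ctse, a cathepsin, rose (217 ± 3.89 against 19.1 ± 3.1 TPM, 10.9-fold), and so did the erythropoietin receptor Epor (8.3 ± 1.94 against 0.676 ± 0.373, 5.55-fold). The platelet integrin Itga2b (75.1 ± 3.61 against 22.3 ± 1.41, 3.27-fold) was higher, as were the homeobox genes Hoxa9 (69.6 ± 4.83 against 33.2 ± 1.16) and Meis1 (269 ± 19.2 against 147 ± 11.9). They held less of monocyte, dendritic and B cell genes. Pld4, an exonuclease of plasmacytoid dendritic cells, fell (9.54 ± 1.56 against 277 ± 11.8, log2 -4.73), and so did Ly86 (7.39 ± 2.19 against 123 ± 14.5, log2 -3.91). Lower as well were Ly6c2 (159.9 ± 62 against 1494 ± 71.5, log2 -3.30), Irf8 (55.3 ± 8.13 against 235 ± 5.45) and the DNA polymerase Dntt (45 ± 8.21 against 172 ± 17.8). The receptor genes Mrgpra2a and Mrgpra2b fell by 3.66 and 3.68 on the log2 scale, and the keratinocyte gene Dmkn was 4.7 ± 0.17 against 105 ± 9.5 TPM. Prss34, a basophil protease, averaged 47.1 ± 43.6 TPM in T2 and was listed at 0 in all 3 T1 libraries (adjusted p = 0.0229). This call was lost with the spread of each table alone or only the groups compared (adjusted p = 0.111) and without T1 replicate 1, 2 or 3 (adjusted p = 0.0854, 0.0843 and 0.0686).

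B cell genes fell together, 11 lower and none higher of 12 (also adjusted over the list alone, adjusted p = 2.04e-18, and adjusted p = 0.000495 with an estimated correlation). Vpreb1 was 28.4 ± 7.52 against 207 ± 55.1 TPM and Ebf1, a B lineage factor, 2.74 ± 0.277 against 18.4 ± 5.28. Neutrophil and monocyte primed genes were lower in 12 and higher in 4 of 26 (14 and 4 adjusted over the list alone, adjusted p = 2.54e-12, and adjusted p = 0.000495 with an estimated correlation). Clec12a among them was 34.5 ± 10.8 against 129 ± 4.29. Lymphoid primed genes were lower in 10 and higher in 2 of 22 (11 and 2 adjusted over the list alone, adjusted p = 1.76e-05, and adjusted p = 0.00449 with an estimated correlation). Il7r, the interleukin 7 receptor, was 2.41 ± 1.54 against 14 ± 0.695 TPM. Dendritic cell genes fell, 7 lower and none higher of 16 (also adjusted over the list alone, adjusted p = 1.29e-08, and adjusted p = 0.000651 with an estimated correlation). Genes of T, NK and innate lymphoid cells fell too, 6 lower and 1 higher of 18 (7 and 1 adjusted over the list alone, adjusted p = 6.47e-06, and adjusted p = 0.000495 with an estimated correlation).

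Handling of cells can raise immediate early and heat shock genes. These were lower in 7 and higher in none of 20 in T2 cells of 3-month WTiMOS MPP3 (9 and 0 adjusted over the list alone, adjusted p = 3.38e-10, and adjusted p = 0.000927 with an estimated correlation). Fos was 1719 ± 147 against 3336 ± 50.4 TPM and Atf3 was 18.1 ± 4.63 against 60.9 ± 12.3. The p53 list passed as lower, with 4 lower and 1 higher of 20 (5 and 2 adjusted over the list alone, adjusted p = 0.00451, and adjusted p = 0.0181 with an estimated correlation). So did the proliferation list, with 5 lower and none higher of 30 (8 and 0 adjusted over the list alone, adjusted p = 0.000136, and adjusted p = 0.0441 with an estimated correlation).

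Stem cell and quiescence genes rose in T2 cells of 3-month WTiMOS MPP3, 12 higher and 1 lower of 26 (13 and 1 adjusted over the list alone, adjusted p = 1.24e-05, and adjusted p = 0.028 with an estimated correlation). Hlf was 44.9 ± 3.78 against 20.3 ± 0.972 TPM. Erythroid genes rose, 12 higher and none lower of 22 (12 and 1 adjusted over the list alone, adjusted p = 5.43e-07, and adjusted p = 0.00613 with an estimated correlation). Megakaryocyte and platelet genes did too, 6 higher and none lower of 16 (the same adjusted over the list alone, adjusted p = 0.00103, and adjusted p = 0.00514 with an estimated correlation). Myc target genes rose as well, 7 higher and none lower of 30 (9 and 0 adjusted over the list alone, adjusted p = 0.000505, and adjusted p = 0.00449 with an estimated correlation). The macrophage list had 7 higher and 9 lower of 19 (8 and 9 adjusted over the list alone). Its median was 0.33, its mean -0.16 and its test towards lower (adjusted p = 0.015, and adjusted p = 0.0449 with an estimated correlation). Mature neutrophil genes were lower in 5 and higher in 1 of 15 (the same adjusted over the list alone, adjusted p = 2.29e-05), a call lost at adjusted p = 0.0552 with an estimated correlation. Genes reported to respond to Bcl11a, 4 lower and 2 higher of 13 (the same adjusted over the list alone), passed at adjusted p = 0.00948 and were lost at adjusted p = 0.116 with an estimated correlation. Ribosomal protein genes, 15 lower and none higher of 83 (18 and 0 adjusted over the list alone), were likewise lost (adjusted p = 1.58e-14, and adjusted p = 0.117 with an estimated correlation). Rpl10 was 1514 ± 65 against 2102 ± 85.9.

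The test called 1562 of 11723 genes in 3-month WTiMOS MPP3, 937 higher and 625 lower, and 534 by at least 2-fold. The median of all genes lay at log2 0.10, and the balance turned to 570 higher and 901 lower after median-ratio rescaling. Without T1 replicate 1 the count was 811 and without T1 replicate 2 it was 909, and 1189 genes were called in the same direction with the spread of this table alone.

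In WTiMOS MPP3 of 24 months the comparison of T2 with T1 cells asked the same at an older age. T1 cells held far more RNA of Dmkn (6.75 ± 0.277 TPM in T2 against 919 ± 21.8 in T1, log2 -6.89) and Trat1, an adaptor of the T cell receptor (8.49 ± 1.23 against 363 ± 28.4, log2 -5.27). The same held for Mrgpra2a (11.5 ± 3.58 against 251 ± 16.3) and Mrgpra2b (20.3 ± 5.25 against 566 ± 28.6). They also held more of the granule protease Ctsg (718 ± 19.6 against 3278 ± 171) and S100a8, a calcium-binding protein of neutrophils (236 ± 29.2 against 1959 ± 166). Cpa3 (383 ± 35.6 against 2037 ± 134) and Ccl4 (722 ± 114 against 3229 ± 73) were also lower in T2. T2 cells were higher in Jchain, the joining chain of immunoglobulins (2577 ± 441 against 13.2 ± 1.29, 179.9-fold). Procr, a surface marker of stem cells (16.5 ± 1.28 against 2.39 ± 0.415, 5.2-fold), and Esam (15.2 ± 1.58 against 2.28 ± 0.575, 4.98-fold) rose too. Eif2s3y was 39.9 ± 6.95 TPM in T2 and listed at 0 in all 3 T1 libraries, and Xist was 20.4 ± 2.23 against 69.2 ± 7.36.

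Stem cell and quiescence genes rose in 21 and fell in 2 of 23 (the same adjusted over the list alone, adjusted p = 2.29e-07, and adjusted p = 0.0369 with an estimated correlation). Hlf was 37 ± 6.41 against 8.45 ± 2.21 TPM and Meis1 57.3 ± 3.73 against 20.8 ± 1.94. Myc target genes were higher in 18 and lower in 2 of 30 (also adjusted over the list alone, adjusted p = 0.00639, and adjusted p = 0.0369 with an estimated correlation). Fbl, a nucleolar methyltransferase, was 220.3 ± 6.96 against 95.5 ± 6.16. Genes primed for neutrophils and monocytes fell, 14 lower and 1 higher of 26 (the same adjusted over the list alone, adjusted p = 1.96e-11, and adjusted p = 0.00182 with an estimated correlation). Clec12a was 45.4 ± 8.45 against 714 ± 32.9 TPM and the haptoglobin gene Hp 15.5 ± 1.74 against 269 ± 29.6. Erythroid genes were higher in 16 and lower in 2 of 21 (17 and 2 adjusted over the list alone), a call lost at adjusted p = 0.0888 with an estimated correlation. Haematopoietic transcription factors, 24 higher and 7 lower of 48 (the same adjusted over the list alone), did not pass (adjusted p = 0.0614).

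Of 11317 genes tested 5214 differed between T2 and T1 cells of 24-month WTiMOS MPP3, 3703 higher and 1511 lower, and 1151 by at least 2-fold. The median of all genes lay at log2 0.18, and median-ratio rescaling gave 2417 higher and 2371 lower. With the spread of this table alone 4560 of the calls were made in the same direction.

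MPP4 of WTiMOS mice was compared in the same way, the question being the role of Bcl11a within this subset. At 3 months most genes were lower in T2 than in T1 cells, with a median of all genes at log2 -0.74, so changes are also given after median-ratio rescaling. The T2 libraries stood apart from T1, with 10519 to 10660 genes at 1 TPM against 11375 to 11474, and 35.8 ± 0.217% against 26.7 ± 0.0968% of all TPM in the 100 most abundant genes. On the first principal component they lay at -106 to -99.6 against -46.0 to -42.9. Ribosomal protein genes went up against this shift, Rps24 from 869.9 ± 45.4 TPM in T1 to 1765 ± 123 in T2 (log2 1.02, rescaled 1.93). Rpl24 went from 704 ± 23.1 to 1318 ± 60.3 (log2 0.90, rescaled 1.82). Wfdc17 rose to 5268 ± 121 TPM (log2 2.39, rescaled 3.31) and Cd52, a lymphocyte surface protein, to 1175 ± 10.1 (log2 1.37, rescaled 2.28). Lower in T2 under both scalings were the monocyte genes Ly6c2 (20.2 ± 4.22 against 166 ± 3.64 TPM, log2 -2.99, rescaled -2.11) and F13a1 (0.207 ± 0.0442 against 10.1 ± 1.41, log2 -3.19, rescaled -2.93). So were Mrgpra2a (0.558 ± 0.172 against 20.9 ± 0.974, rescaled log2 -3.38), Mrgpra2b (0.676 ± 0.382 against 31.3 ± 1.91, rescaled log2 -3.83) and Dntt (393 ± 41 against 974 ± 9.24, log2 -1.31, rescaled -0.40). Flt3 was 116 ± 6.12 against 179.7 ± 5.81 TPM (log2 -0.63), which turned to 0.28 with rescaling. Eif2s3y was 75.2 ± 5.89 TPM in T2 and listed at 0 in T1.

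Cytosolic ribosomal protein genes were higher in 71 and lower in 6 of 84 (the same adjusted over the list alone, and 81 and 1 rescaled), the list's adjusted p = 1.66e-55, and adjusted p = 0.014 with an estimated correlation. Rpl3 was among the lower, at 1154 ± 50.3 against 2549 ± 40.3 TPM. Nuclear genes of oxidative phosphorylation were higher in 22 and lower in 12 of 35 (the same adjusted over the list alone, and 26 and 6 rescaled, adjusted p = 4.06e-11, and adjusted p = 0.0105 with an estimated correlation). Uqcrc1 (76.5 ± 6.12 against 383 ± 45.3) and Atp5b (269 ± 14.2 against 1044 ± 90.4), of the respiratory chain and the ATP synthase, were among those lower. Erythroid genes split 4 higher and 4 lower of 12 (4 and 3 adjusted over the list alone, and 8 and 1 rescaled). Their median was -0.18, their mean 0.89 and their test towards higher (adjusted p = 0.0162, and adjusted p = 0.0448 with an estimated correlation). Proliferation genes were lower in 29 and higher in none of 30 (also adjusted over the list alone, and 15 lower and 5 higher rescaled, adjusted p = 0.000249), lost at adjusted p = 0.0844 with an estimated correlation. The kinase Aurka was 9.62 ± 2.31 against 63.5 ± 4.43 and Cdc20 19.3 ± 2.06 against 104 ± 17.2 TPM. Glycolysis genes were lower in 19 and higher in none of 21 (the same adjusted over the list alone, and 11 lower and 2 higher rescaled, adjusted p = 0.00328), lost at adjusted p = 0.235 with an estimated correlation. Pkm, a pyruvate kinase, was 49 ± 4.69 against 162 ± 15.7. The list of sex genes passed both ways (4 higher and 1 lower of 5, adjusted p = 8.11e-08, and adjusted p = 0.00208 with an estimated correlation).

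The test called 9160 of 11288 genes in 3-month WTiMOS MPP4, 944 higher and 8216 lower, and 3838 by at least 2-fold. Rescaling left 6132, 3333 higher and 2799 lower, of which 913 went the opposite way to the call before it. Removing a trend on GC content and length left 5824. With the spread of this table alone 8979 of the 9160 calls were made in the same direction.

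MPP4 of 24 months moved the other way as a whole, with a median of log2 0.43 over all genes. Here the libraries stood apart as well, T2 with 11466 to 11498 genes at 1 TPM against 10868 to 10877 in T1. The 100 most abundant genes took 26.4 ± 0.122% of all TPM in T2 against 30.4 ± 0.218% in T1. On the first principal component T2 lay at -45.3 to -38.2 against -74.0 to -67.3. T2 cells were higher in Ctse (91.3 ± 14 against 12.3 ± 0.433 TPM, log2 2.79, rescaled 2.38) and Pglyrp1, a peptidoglycan receptor (63.7 ± 0.975 against 10 ± 1.01, log2 2.56, rescaled 2.15). Higher too were Emcn, a sialomucin of stem and endothelial cells (31.5 ± 2.64 against 4.81 ± 0.821, rescaled log2 2.11) and Hlf (44.1 ± 5.92 against 9.57 ± 1.17, rescaled log2 1.69). T1 cells held more Trat1 (1.31 ± 0.807 in T2 against 117 ± 9.33 in T1, log2 -5.74) and Ly6c2 (13.4 ± 0.461 against 167 ± 11.9, log2 -3.54). They held more of the lectin Lgals1 (183 ± 8.72 against 1408 ± 51.6, log2 -2.94) and the metallothionein Mt1 (49.2 ± 10.6 against 286 ± 10.6). Ctsg (367 ± 21.9 against 1248 ± 32.1) and Ccl4 (1414 ± 69.9 against 4335 ± 56.9) fell in T2 as well. Mrgpra2a and Mrgpra2b fell by 3.37 and 3.56 on the log2 scale, and Eif2s3y was 111 ± 4.59 TPM in T2 with a T1 mean of 0.0816.

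Among 25 neutrophil and monocyte primed genes 10 were lower and 7 higher (the same adjusted over the list alone, and 14 and 6 rescaled, adjusted p = 6.61e-09, and adjusted p = 0.00306 with an estimated correlation). Ly86 was 18 ± 0.81 against 127 ± 5.25 TPM. Ribosomal protein genes were lower in 51 and higher in 5 of 85 (50 and 5 adjusted over the list alone, and 80 and 1 rescaled, adjusted p = 2.28e-33, and adjusted p = 0.0261 with an estimated correlation). Oxidative phosphorylation genes were lower in 21 and higher in 5 of 35 (21 and 6 adjusted over the list alone, and 30 and 1 rescaled, adjusted p = 1.18e-13, and adjusted p = 0.00306 with an estimated correlation). Cox5a was 1007 ± 124 against 1425 ± 15.3. Proliferation genes were lower in 8 and higher in 4 of 30 (7 and 3 adjusted over the list alone, and 22 and 0 rescaled, adjusted p = 6.76e-09, and adjusted p = 0.00648 with an estimated correlation). Birc5 was 395 ± 16.8 against 685 ± 18.2. The stem cell ageing list was lower in 7 and higher in 6 of 17 (the same adjusted over the list alone, and 8 and 2 rescaled, adjusted p = 9.81e-07, and adjusted p = 0.00263 with an estimated correlation). Stem cell and quiescence genes were higher in 19 and lower in 2 of 22 (the same adjusted over the list alone, and 15 and 2 rescaled, adjusted p = 0.000666), a call lost at adjusted p = 0.0954 with an estimated correlation. Txnip was 244 ± 16.7 against 66.8 ± 6.24 and Meis1 69.3 ± 0.435 against 31.5 ± 0.892.

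In 24-month WTiMOS MPP4 7685 of 11366 genes differed, 6882 higher and 803 lower in T2, and 885 by at least 2-fold. Rescaling left 4420, 2218 higher and 2202 lower, and removing a trend on GC content and length left 3897. With the spread of this table alone 7157 of the 7685 calls were made in the same direction.

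**Figure D3:**
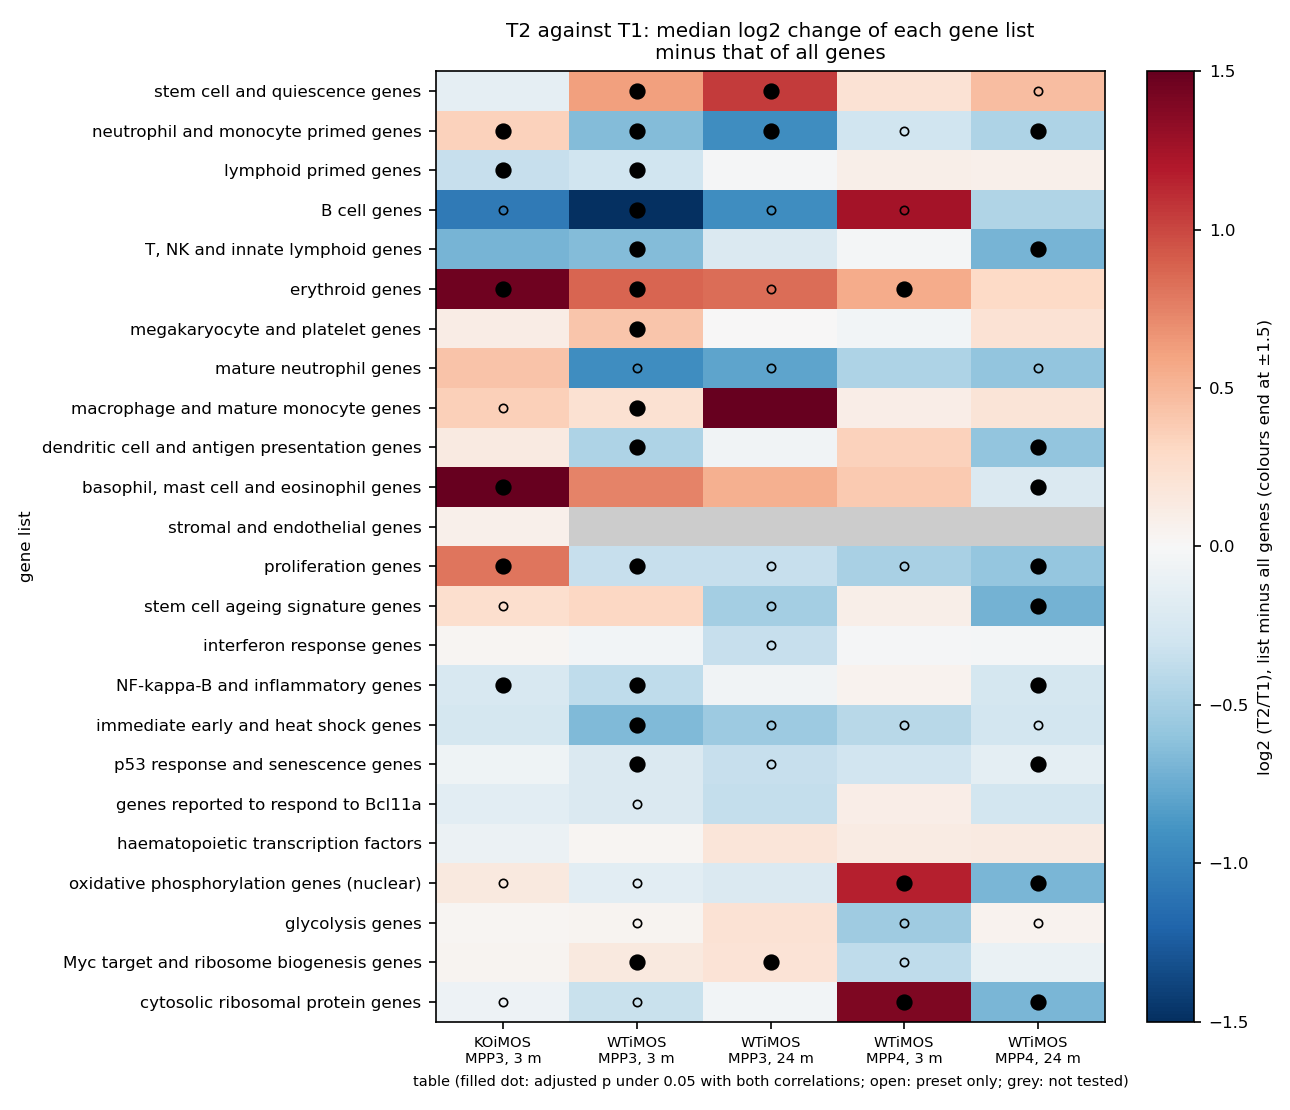
Colour gives the median log2 change of T2 against T1 of each fixed gene list minus that of all genes, with a line per list and a column per table; a filled dot marks a list called with both the preset and the estimated correlation, an open dot one called with the preset only, and grey a list not tested. Neutrophil and monocyte primed genes lie above the other genes in KOiMOS MPP3 (0.35) and below them in 24-month WTiMOS MPP3 (-0.93), and ribosomal protein genes lie above them in 3-month MPP4 (1.40) and below them in 24-month MPP4 (-0.69).

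How far the step from T1 to T2 differed between KOiMOS and WTiMOS MPP3 of 3 months was tested as a difference of differences. Bcl11a rose in WTiMOS and not in KOiMOS, a difference of log2 -0.82 (adjusted p = 0.000659). Cpa3 averaged 247 TPM in T1 and 974 in T2 of KOiMOS but 235 and 135 of WTiMOS (difference 2.77). Clec12a averaged 20 and 47.9 against 129 and 34.5 (difference 3.13). Proliferation genes differed towards KOiMOS in 23 and towards WTiMOS in none of 30 (also adjusted over the list alone, adjusted p = 9.6e-23, and adjusted p = 0.000117 with an estimated correlation). So did neutrophil and monocyte primed genes in 16 and 1 of 26 (16 and 2 adjusted over the list alone, adjusted p = 4.67e-16, and adjusted p = 0.000131 with an estimated correlation). B cell genes did in 7 and 0 of 13 (8 and 0 adjusted over the list alone, adjusted p = 3.53e-06, and adjusted p = 0.0383 with an estimated correlation). As a list they were lower in T2 cells of both tables, so this was a smaller fall in KOiMOS and not a rise. Stem cell and quiescence genes differed towards WTiMOS, 11 lower and 1 higher of 26 (15 and 1 adjusted over the list alone, adjusted p = 2.33e-05, and adjusted p = 0.0457 with an estimated correlation). In all 2442 of 12609 genes differed, 962 higher and 1480 lower in KOiMOS, which turned to 1347 higher and 927 lower with rescaling. Only 1556 were called without T1 replicate 1 of the WTiMOS table.

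Between 24 and 3 months the T2 and T1 difference of WTiMOS MPP3 differed most in genes of the Y chromosome. Eif2s3y averaged 52.9 TPM in T1 and 30.1 in T2 at 3 months and was listed at 0 in T1 at 24 months. Among autosomal genes, Gstm1, a glutathione transferase, averaged 366 and 205 TPM in T1 and T2 at 3 months and 2486 and 285 at 24 months (difference -2.29). Ctss, a cathepsin of antigen processing, averaged 105 and 22.1, then 87.9 and 124 (difference 2.68). The step in Bcl11a was larger at 24 months by log2 0.95 (adjusted p = 0.00104). Macrophage genes differed towards 24 months in 8 and towards 3 months in none of 21 (11 and 0 adjusted over the list alone, adjusted p = 0.000184, and adjusted p = 0.0155 with an estimated correlation). Stem cell ageing genes differed towards 3 months in 7 and 24 months in 2 of 24 (9 and 3 adjusted over the list alone, adjusted p = 0.000911, and adjusted p = 0.0292 with an estimated correlation). The test called 2011 genes, 1283 higher and 728 lower at 24 months, and 1115 and 938 after rescaling.

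For MPP4 the same test across age gave Eef2, an elongation factor, at 356 and 45.1 TPM in T1 and T2 of 3 months and 145 and 362 of 24 months (difference 4.27, rescaled 2.95). Ptbp1, a splicing regulator, was at 32.3 and 2.57, then 10.6 and 31.1 (difference 4.69, rescaled 3.57). The difference for Bcl11a was 0.66 (adjusted p = 0.000265) and turned to -0.66 with rescaling. Ribosomal protein genes differed towards 3 months in 71 and 24 months in 6 of 85 (the same adjusted over the list alone, adjusted p = 4.78e-64, and adjusted p = 0.00912 with an estimated correlation). So did oxidative phosphorylation genes in 22 and 10 of 35 (the same adjusted over the list alone, adjusted p = 6.91e-16, and adjusted p = 0.00329 with an estimated correlation). All genes had a median of 1.16, and 9858 were called, 9019 higher and 839 lower at 24 months. After rescaling 5869 were called, 2985 higher and 2884 lower, 937 of them opposite to the first call, and 5652 after removing a trend on GC content and length.

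Across cell types at 3 months, the T2 and T1 difference of MPP4 differed from that of MPP3 in Cd52, at 307 and 106 TPM in T1 and T2 of MPP3 and 455 and 1175 of MPP4 (difference 2.89). It differed also in Snw1, a splicing cofactor, at 413 and 501, then 172 and 22.6 (difference -3.16, rescaled -2.15). B cell genes differed towards MPP4 in 10 and towards MPP3 in none of 13 (also adjusted over the list alone, adjusted p = 5.23e-13, and adjusted p = 0.00206 with an estimated correlation). Ribosomal protein genes did so in 73 and 4 of 85 (the same adjusted over the list alone, adjusted p = 3.64e-55, and adjusted p = 0.00829 with an estimated correlation). Myc target genes differed towards MPP3 in 26 and MPP4 in 2 of 30 (the same adjusted over the list alone, and 14 and 5 rescaled, adjusted p = 5.62e-05, and adjusted p = 0.00206 with an estimated correlation). For Bcl11a the difference did not pass (log2 -0.07, adjusted p = 0.764), and it was 0.95 with rescaling (adjusted p = 0.000188). The test called 8176 genes, 887 higher and 7289 lower in MPP4 about a median of -0.81. Rescaling left 4591, 2605 higher and 1986 lower, with 281 opposite to the first call, and 4416 were called after removing a trend on GC content and length.

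At 24 months the 2 cell types differed in the step from T1 to T2 for Gstm1, at 2486 and 285 TPM in T1 and T2 of MPP3 and 435 and 492 of MPP4 (difference 3.30). They differed also for Clec12a, at 714 and 45.4, then 230.5 and 101 (difference 2.77). Genes primed for neutrophils and monocytes differed towards MPP4 in 13 and towards MPP3 in none of 26 (also adjusted over the list alone, adjusted p = 6.87e-05, and adjusted p = 0.0319 with an estimated correlation). Erythroid genes differed towards MPP3 in 6 and MPP4 in 1 of 21 (9 and 2 adjusted over the list alone, adjusted p = 1.81e-06, and adjusted p = 0.0104 with an estimated correlation). The difference for Bcl11a was -0.36 (adjusted p = 0.107) and passed with rescaling at -0.61 (adjusted p = 0.0122). It passed as well without 24-month MPP3 T1 replicate 2 (adjusted p = 0.0486) or T2 replicate 3 (adjusted p = 0.044). The test called 2828 genes, 2239 higher and 589 lower in MPP4, and 1003 and 1213 after rescaling.

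The effect of age was read from WTiMOS MPP3, T1 and T2 together. H2-Eb1, a gene of MHC class II, was higher at 24 months (81.7 ± 6.26 against 3.44 ± 1.21 TPM at 3 months, 19.2-fold, chromosome 17, positions 34305867 to 34316674, GRCm38). So were H2-Aa (165 ± 9.83 against 18 ± 5.96, 9.14-fold) and H2-Ab1 (514 ± 93.6 against 83.3 ± 5.47, 6.04-fold). Aldh1a1, an aldehyde dehydrogenase (32.7 ± 11.6 against 1.01 ± 0.999), and Plscr2, a phospholipid scramblase (23.5 ± 10.8 against 0.869 ± 1.08), were higher too. Lower at 24 months were Mpo (238 ± 50.4 against 3214 ± 1139.7, log2 -3.70) and Bcl11a (25.1 ± 15.8 against 61.8 ± 18.7, log2 -1.47). Genes that most cells use differed as much or more. Taf10, a subunit of the general transcription factor TFIID, was 67.9-fold higher (158 ± 24.6 against 1.49 ± 1.01). The lysosomal gene Psap was lower by log2 -6.47 (5.13 ± 1.28 against 575 ± 238).

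No list kept its call in 24-month against 3-month MPP3 with an estimated correlation. Stem cell ageing genes were higher in 15 and lower in 3 of 24 (the same adjusted over the list alone, adjusted p = 0.00152), lost at adjusted p = 0.0609 with an estimated correlation. Of 35 oxidative phosphorylation genes 25 were higher and 9 lower (the same adjusted over the list alone, adjusted p = 4.26e-07), also lost at adjusted p = 0.0609 with an estimated correlation. Cox7b, a subunit of cytochrome oxidase, was 757 ± 107 against 95.1 ± 11.7 TPM. The test called 10277 genes, 3442 higher and 6835 lower at 24 months about a median of log2 -0.50, and 6103 by at least 2-fold. After rescaling 5002 were higher and 5181 lower. Across genes the change followed GC content (Pearson's r = -0.37, genes not being independent replicates), with medians from 0.16 in the fifth of genes lowest in GC to -1.29 in the highest. Each age was a single table, so the age and whatever else differed between the tables cannot be told apart.

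**Figure D4:**
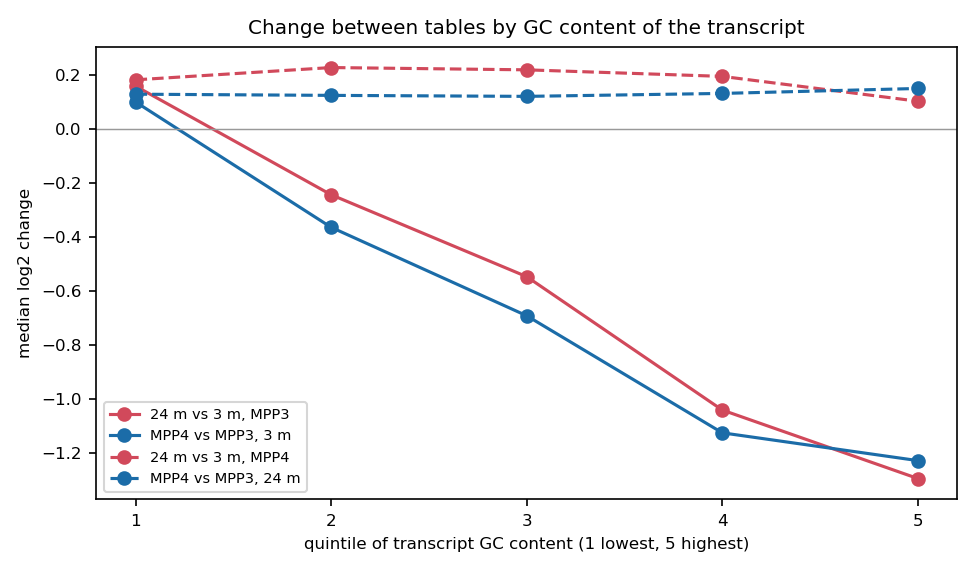
Median log2 change (y axis) of genes in 5 equal groups by GC content (x axis, lowest to highest), with a line for each comparison named in the key. The lines of 24-month against 3-month MPP3 and of MPP4 against MPP3 at 3 months run from 0.16 to -1.29 and from 0.10 to -1.23, while those of the other comparisons move less.

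In MPP4 the genes higher at 24 months were among others H2-Eb1 (128 ± 20.6 against 13.2 ± 2.25 TPM, 9.09-fold), H2-Ab1 (830.5 ± 63.2 against 173 ± 35.7, 4.85-fold) and Cd74, a chaperone of MHC class II (484 ± 83.9 against 95.1 ± 33.6, 5.23-fold). Aldh1a1 (6.04 ± 1.1 against 0.363 ± 0.437) and Plscr2 (9.17 ± 1.65 against 0.339 ± 0.441) were higher as well. Lower at 24 months were Il7r (3.64 ± 1.06 against 13.3 ± 0.887, log2 -1.66) and Ly6d, a marker of early lymphoid cells (62.9 ± 37.1 against 249 ± 133, log2 -2.01). Jchain (12.4 ± 12.5 against 125 ± 65.7, log2 -3.99) and Bcl11a (45.9 ± 23 against 52.2 ± 14.3, log2 -0.30, rescaled -0.59, adjusted p = 0.0018) were lower too. Without rescaling the fall of Bcl11a lay in T1 cells (log2 -0.63, adjusted p = 2.66e-05), and within T2 cells it did not pass (log2 0.03, adjusted p = 0.775). With rescaling the difference of its T2 and T1 step across age turned from 0.66 to -0.66, so which cells held the fall depended on the scaling. Proliferation genes were higher in 29 and lower in none of 30 (also adjusted over the list alone, and 22 and 1 rescaled, adjusted p = 3.74e-11, and adjusted p = 0.00459 with an estimated correlation). Within T2 cells, whose 3-month libraries stood apart, 27 were higher and 1 lower, but within T1 cells 11 and 2. Their median was log2 1.22 within T2 cells, where that of all genes was 0.77, and 0.18 within T1 cells, where it was -0.37. Against the other genes they were thus higher in both. Ccnb1, a mitotic cyclin, was 222 ± 45.5 against 111 ± 60.6. Myc target genes were higher in 28 and lower in 1 of 30 (the same adjusted over the list alone, and 13 and 4 rescaled, adjusted p = 1.47e-07, and adjusted p = 0.000308 with an estimated correlation). Within T2 cells 26 of them were higher and 2 lower (median log2 1.20), and within T1 cells 5 higher and 15 lower (median -0.19). Both medians lay above those of all genes in the same cells. Ncl, nucleolin, was 244 ± 11.2 against 138 ± 77 (log2 1.88 within T2 and 0.17 within T1 cells). The test called 5970 genes, 4893 higher and 1077 lower, and 212 by at least 2-fold, about a median of log2 0.18, and after rescaling 2009 higher and 3120 lower. Within T1 cells 727 genes were higher and 6263 lower, and within T2 cells 8551 and 958, so the pooled change joined opposite shifts. As in MPP3, age and table cannot be told apart.

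MPP4 was set against MPP3 of WTiMOS mice at 3 months as a comparison of the cell types. MPP4 held more Dntt (683 ± 319.6 against 109 ± 70.8 TPM, 6.98-fold), Il12a, a cytokine subunit (828 ± 82.7 against 81.1 ± 13.2, 10.2-fold), and Ccl3 (2295 ± 685 against 84.7 ± 31.4, 27.3-fold). It held less of the granule genes Elane (42.7 ± 15.9 against 2290.2 ± 862, log2 -5.69) and Mpo (46 ± 15 against 3214 ± 1139.7, log2 -6.08). Cpa3 (13.9 ± 2.53 against 185 ± 55.7, log2 -3.60) and Itga2b (0.667 ± 0.402 against 48.7 ± 29) were lower in MPP4 too. Taf10 was 80.2-fold higher and Rbm38, an RNA-binding protein, lower by log2 -7.50 (2.4 ± 0.511 against 611 ± 62.4), so genes outside the lineages differed as much. Bcl11a was 52.2 ± 14.3 against 61.8 ± 18.7 TPM (log2 -0.23, adjusted p = 0.0237), which turned to 0.43 with rescaling. It did not pass within T1 (adjusted p = 0.178) or within T2 cells (adjusted p = 0.0652) alone. The call was lost after removing a trend on GC content and length (adjusted p = 0.251), and without MPP3 T1 replicate 2 (adjusted p = 0.0746), MPP3 T2 replicate 2 (adjusted p = 0.067) or MPP4 T1 replicate 3 (adjusted p = 0.0592).

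Lymphoid primed genes were higher in MPP4 of 3 months in 18 and lower in 5 of 23 (the same adjusted over the list alone, adjusted p = 0.000428), a call lost at adjusted p = 0.0702 with an estimated correlation. Of 26 neutrophil and monocyte primed genes 21 were lower and 4 higher (the same adjusted over the list alone, adjusted p = 0.00835), lost at adjusted p = 0.248 with an estimated correlation. The test called 10450 genes, 3395 higher and 7055 lower about a median of log2 -0.58, and 6413 by at least 2-fold, and after rescaling 5151 higher and 5243 lower. The change again followed GC content across genes (Pearson's r = -0.32), and cell type and table cannot be told apart.

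At 24 months MPP4 held more Dntt (663 ± 51.1 against 71.3 ± 18.8 TPM in MPP3, 9.43-fold), Flt3 (154 ± 45.9 against 23.9 ± 4.77, 6.09-fold) and Il12a (582 ± 27.8 against 100 ± 26.1, 5.94-fold). Bcl11a was higher as well (45.9 ± 23 against 25.1 ± 15.8, log2 0.94, adjusted p = 2.51e-10). It held less Elane (32.3 ± 21.8 against 1816 ± 1713, log2 -5.19), Ms4a3 (8.59 ± 1.62 against 262 ± 73.9, log2 -4.75) and Cpa3 (67.3 ± 56.3 against 1210.0 ± 910.1, log2 -4.29), and of B cell genes Vpreb3 (2.1 ± 2.44 against 81.8 ± 72, log2 -4.40). Fcer1a, the IgE receptor, was 90.2 ± 30.7 TPM in MPP3 and listed at 0 in every MPP4 library. Lymphoid primed genes rose in 18 and fell in 2 of 23 (the same adjusted over the list alone, adjusted p = 1.36e-09, and adjusted p = 0.000267 with an estimated correlation). Interferon response genes rose in 24 and fell in none of 32 (also adjusted over the list alone, adjusted p = 1.26e-07, and adjusted p = 0.0011 with an estimated correlation). Neutrophil and monocyte primed genes were lower in 17 and higher in 2 of 26 (the same adjusted over the list alone, adjusted p = 5.16e-16, and adjusted p = 9.55e-05 with an estimated correlation). So were basophil and mast cell genes in 15 and 0 of 19 (16 and 0 adjusted over the list alone, adjusted p = 7.14e-22, and adjusted p = 4.28e-05 with an estimated correlation). Erythroid genes were lower in 16 and higher in 1 of 21 (the same adjusted over the list alone, adjusted p = 1.89e-11, and adjusted p = 0.000209 with an estimated correlation). Stem cell ageing genes were lower in 13 and higher in 1 of 23 (the same adjusted over the list alone, adjusted p = 3.8e-10, and adjusted p = 9.55e-05 with an estimated correlation). The test called 5328 genes, 3990 higher and 1338 lower in MPP4 about a median of log2 0.13, and 373 by at least 2-fold, and after rescaling 2055 higher and 2714 lower. Within T1 cells 2568 genes were called and within T2 cells 5528. Erythroid genes were lower in 7 and higher in 1 within T1 cells, and 17 and 2 within T2 cells. Neutrophil and monocyte primed genes were lower in 18 and higher in 2 within T1 cells, and 12 and 6 within T2 cells. Here too cell type and table cannot be told apart.

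KOiMOS and WTiMOS MPP3 of 3 months were compared within T1 cells. Pld4 (5.86 ± 0.436 TPM in KOiMOS against 277 ± 11.8 in WTiMOS, log2 -5.34) and Ly6d (2.03 ± 1.27 against 80.8 ± 9.99, log2 -4.84), genes of dendritic and early lymphoid cells, were lower in KOiMOS. Cd177, a neutrophil surface protein, was listed at 0 in all 3 KOiMOS libraries and was 58.4 ± 11 TPM in WTiMOS. Tpsb2 was 62.2 ± 5.76 TPM in KOiMOS and listed at 0 in all 3 WTiMOS libraries. Bcl11a was 70.3 ± 2.48 against 45.2 ± 2.79 (log2 0.63, adjusted p = 4.55e-05). The translation factor subunit Eif3f, which most cells need, was 8.92 ± 0.557 against 876 ± 24.4 TPM. Of 26 genes primed for neutrophils and monocytes 18 were lower in KOiMOS and 4 higher (18 and 5 adjusted over the list alone, adjusted p = 3.31e-08, and adjusted p = 0.00476 with an estimated correlation). Of 12 B cell genes 11 were lower and 1 higher (the same adjusted over the list alone, adjusted p = 2.8e-08, and adjusted p = 0.015 with an estimated correlation). Immediate early genes were lower in 18 and higher in 2 of 21 (the same adjusted over the list alone, adjusted p = 6.79e-11, and adjusted p = 0.00302 with an estimated correlation). Proliferation genes were lower in 23 and higher in 2 of 30 (25 and 2 adjusted over the list alone, adjusted p = 1.49e-09, and adjusted p = 0.00476 with an estimated correlation). Megakaryocyte genes were higher in 13 and lower in 2 of 17 (the same adjusted over the list alone, adjusted p = 0.0176, and adjusted p = 0.0385 with an estimated correlation). The test called 7345 genes, 4327 higher and 3018 lower in KOiMOS, and 3410 and 3980 after rescaling, about a median of log2 0.13. Genotype and table cannot be told apart.

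Within T2 cells Mcpt4 (491 ± 30.5 TPM in KOiMOS against 1.76 ± 1.59 in WTiMOS, 209-fold), Cma1 (1075 ± 39.4 against 14.7 ± 18.1, 135-fold) and Hbb-b2 (1246 ± 32.6 against 14.2 ± 2.9, 83.2-fold) were higher in KOiMOS. Eif3f (8.87 ± 2.99 against 777 ± 28.1) and Rrs1, a ribosome biogenesis factor (1.71 ± 0.168 against 138 ± 8.88), were lower. Bcl11a did not pass, at 68.2 ± 3.41 against 78.5 ± 6.06 TPM (log2 -0.20, adjusted p = 0.153), and passed as lower in KOiMOS after removing a trend on GC content and length (log2 -0.42, adjusted p = 0.00162). Basophil, mast cell and eosinophil genes were higher in 15 and lower in 3 of 19 (the same adjusted over the list alone, adjusted p = 3.2e-07, and adjusted p = 0.0474 with an estimated correlation). Immediate early genes were lower in 16 and higher in 3 of 21 (the same adjusted over the list alone, adjusted p = 1.15e-05), lost at adjusted p = 0.0502 with an estimated correlation. The test called 7073 genes, 3457 higher and 3616 lower in KOiMOS, and 2037 by at least 2-fold. As in T1 cells, genotype and table cannot be told apart.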

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

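Of the tests of explanations in this part, all but the splits of libraries were chosen only after the result was seen. The bound for the age comparison's test on GC content and length was set before that test was run. The make-up of the splits was also examined only after their counts were seen.

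The results here stand out because a test of the difference itself found the step from T1 to T2 unequal between 2 tables. Between KOiMOS and WTiMOS MPP3 of 3 months 2442 genes differed, among them Paqr5 (log2 -4.35), Pld4 (5.09), Cd209a (4.98), Cpa3 (2.77), Clec12a (3.13), Tpm4 (2.99) and Bcl11a (-0.82). Between 24 and 3 months in WTiMOS MPP3 it was 2011 genes, with Eif2s3y (6.19), Ddx3y (4.66), Gstm1 (-2.29), Ctss (2.68), H2afy (1.503), Hmgn1 (1.44) and Bcl11a (0.95). In WTiMOS MPP4 across age 9858 genes differed, with Eef2 (4.27), Snw1 (3.68), Sae1 (3.98), Ptbp1 (4.69), Spop (3.95), Atxn7l3b (2.84) and Bcl11a (0.66). The median of all genes was 1.16 there. After rescaling 5869 genes were called, 937 of them opposite to the first call, and Bcl11a turned to -0.66. Between MPP4 and MPP3 of 3 months 8176 genes differed, with Eif2s3y (7.10), Snw1 (-3.16), Cd52 (2.89), Sae1 (-3.31), Hmgb3 (-2.86) and Ddx3y (5.28), and at 24 months 2828, with Gstm1 (3.30), Clec12a (2.77), Anxa1 (1.73), Ifngr1 (1.64), Atp8b4 (2.14) and Prss57 (1.998). For the 3-month comparison 4591 genes were called after rescaling, 281 of them opposite to the first call.

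A large part of all genes changed at least 2-fold between 24-month and 3-month WTiMOS MPP3, Taf10 and Psap among them. Removing a trend on GC content and length gave 4303 2-fold calls among 11892 genes, where 6103 were made before. Rescaling, which centres the change of all genes as that removal does, gave 5825. This excludes the trend as fitted, on each gene's longest transcript, as the whole cause. An effect of GC content or length that the fit misses was not excluded. MPP4 cells alone in the 24-month MPP3 tubes are excluded, as 6 of 6 libraries lay below every 24-month MPP4 library for Flt3 and Dntt and above them for Elane. A mixture that held some MPP4 cells could pass this test, so it was not excluded. A library batch shared by the 3-month MPP3 tables remains possible, since the change from 3-month to 24-month WTiMOS MPP3 and that from KOiMOS MPP3 to WTiMOS MPP4 of 3 months, which share no library, correlated at Pearson's r = 0.784 across 13225 genes. A state particular to 3-month MPP3 would give this value too, and table and group cannot be separated.

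In WTiMOS MPP4 of 3 months most genes were lower in T2 cells while ribosomal protein genes were higher. The 100 most abundant genes rose from 25.6% to 35.3% of all TPM, which lowers all others by log2 -0.20 where their median change was -0.74, so a few abundant genes taking more of the total are excluded as the whole cause. A rise spread over the 1000 most abundant genes, from 69.1% to 81.8%, gives -0.76 and was not excluded. A trend on GC content and length gives a median of -0.44 with the total held, of the -0.74 seen, which leaves it open for the genes that fell. For ribosomal protein genes 76 of 84 were called higher after its removal. That removal also centres the change of all genes, which raises this count, so the count does not decide. Their distance from all genes, which centring leaves as it is, fell from log2 1.40 to 0.81. The trend as fitted thus gave a part of that distance and not the whole. An earlier bound on 2-fold calls was met, with 1036 left of the 1723 after rescaling, but it was set aside because both steps centre the change of all genes. No biological explanation was tested apart from the grouping itself.

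Y-linked RNA was absent or nearly absent in T1 cells of 24-month MPP3 and both MPP4 tables. T1 and T2 cells sorted from wholly the same animals are excluded as the source, as 9 of 9 T1 libraries held under 0.1 of the Y-linked RNA of every T2 library of their table. T2 cells of these tables held Xist as well, at means of 20.4, 22.8 and 29.3 TPM, so animals shared in part were not excluded. Genes of the X and Y chromosomes do not make up the calls, at no more than 4.43% of 2-fold calls against 3.14% of tested genes in that table. Nor does the sex of the cells alone set the shared autosomal changes, since 83.2% of 393 genes called the same way in these 3 tables went the same way in 3-month WTiMOS MPP3, whose T1 cells held more Y-linked RNA than its T2 cells. How far it adds to the changes of a table was not tested.

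Regrouping the libraries asked how many genes chance would call. For the 7 comparisons of 3 with 3 libraries the 10 possible splits are too few for a share under 0.05, and only 1 of the 10, the real one, reached the real count. The real count and the highest other were 4417 and 1 in KOiMOS MPP3, 1562 and 6 in WTiMOS MPP3 of 3 months, 5214 and 0 in that of 24 months, 9160 and 0 in MPP4 of 3 months and 7685 and 0 in that of 24 months. KOiMOS against WTiMOS gave 7345 and 1 in T1 cells and 7073 and 4 in T2 cells.

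Among 60 splits drawn for each of the other comparisons, only the real grouping reached its own count in several. These were 24-month against 3-month MPP3 (10277, highest other 6259) and MPP4 against MPP3 at 3 months (10450, 8181) and at 24 months (5328, 3305). A random grouping of these libraries is excluded as the source of these counts. Chance differences between animals or between whole tables are not excluded, as the splits only exchanged these libraries. The real grouping alone reached its own count too for the difference of the T2 and T1 step across age in MPP4 (9858, highest other 7082). The same held for that across cell types at 3 months (8176, 6967). For that between KOiMOS and WTiMOS 2 of the 60 splits gave as many genes (2442, highest other 2649), the other being a table exchanged whole. Splits of a step mix T1 with T2 cells and so remove the steps themselves. They can tell a count from no step in either table but not from equal steps, so they do not decide whether steps differ. Nor do they decide for the difference across age in MPP3, with 3 of 60 (2011, 4738), or that across cell types at 24 months, with 3 of 60 (2828, 7878). For 24-month against 3-month MPP4, with 4 of 60 (5970, 9858), the splits do not decide either.

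Each split regrouped 2 sets of 6 libraries, the tables for a difference of the step and the T1 and T2 cells for the others. All other splits that gave as many genes as the real grouping left at least 1 set unmixed, and so held a real difference between the libraries, which points to structure of the samples. Exchanging the groups of 1 set whole tests another contrast, and for 24-month against 3-month MPP4 it gave the 9858 genes of the difference of the step across age. The 47 drawn splits that mixed both sets called at most 3 genes in any of these comparisons.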

How the results depend on the processing

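Of the 16 gene counts, 12 moved by less than 1.5 times under every setting that kept all libraries, and for the others the cause was not tested. WTiMOS MPP4 of 3 months fell from 9160 to 5824 genes with GC content and length removed, and that of 24 months from 7685 to 4420 with rescaling and 3897 with GC content and length removed. The difference of the T2 and T1 step across age in MPP4 fell from 9858 to 5869 and 5652 in turn, and that across cell types at 3 months from 8176 to 4591 and 4416. List tests called 187 results, 183 with a pseudocount of 0.1, and 94 with an estimated correlation, which by its construction widens the test.

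Directions turned in a few genes. Flt3 in T2 against T1 of 3-month MPP4 went from log2 -0.63 to 0.28 with rescaling and 0.18 with GC content and length removed. The difference of the Bcl11a step across age in MPP4 went from 0.66 to -0.66 and -0.46, and that across cell types at 3 months from -0.07 to 0.95 and 0.67, and without 3m_WTiMOS_MPP4_T1 replicate 1 to 0.000553. Bcl11a in MPP4 against MPP3 of 3 months went from -0.23 to 0.43 with rescaling. At 3 months in WTiMOS MPP3 the Eif2s3y call was lost with a pseudocount of 0.1 (adjusted p = 0.0591). Of 231 gene results 4 changed their call or direction with the omission of 1 library.

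Leaving out 1 library gave 3396 to 4279 genes in KOiMOS MPP3, 811 to 1952 in WTiMOS MPP3 of 3 months and 3925 to 5388 of 24 months, 8323 to 9177 in MPP4 of 3 months and 6777 to 7305 of 24 months. Differences of the step gave 1556 to 2761 (KOiMOS and WTiMOS), 1411 to 2302 (age, MPP3), 9610 to 9831 (age, MPP4), 7518 to 8253 (cell types, 3 months) and 1915 to 3206 (24 months), the one for Bcl11a across cell types at 3 months -0.14 to 0.000553. Age gave 9992 to 10282 in MPP3 and 5545 to 6070 in MPP4, cell type 10175 to 10413 at 3 months and 4665 to 5438 at 24 months, and KOiMOS against WTiMOS 6033 to 6825 in T1 and 6214 to 6691 in T2 cells.

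With the spread of each table alone the calls made in the same direction were 88.0%, 76.1%, 87.5%, 98.0% and 93.1% of the planned calls of T2 against T1 (KOiMOS MPP3, WTiMOS MPP3 of 3 and 24 months, MPP4 of 3 and 24 months). They were 84.3%, 88.2%, 99.1%, 95.8% and 85.9% for the differences of the step and at least 93.6% for the rest. Same-numbered replicates of T1 and T2 did not pair, with 0 of 15 correlations over 0.1 (-0.165 to 0.0991). Replicate number as a block gave 4052 genes in KOiMOS MPP3 and 1616 in WTiMOS MPP3 of 3 months, and changed no call of a named gene. TPM carry no depth, so what depth limits was not tested.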

Other observations

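All tests in this part were chosen only after the result was seen.

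After rescaling, 175 of 10532 genes changed the same way between T2 and T1 cells in all 4 WTiMOS tables, 73 higher and 102 lower, where independent lists would give 13.9. Log2 changes are given in the order MPP3 of 3 and 24 months, then MPP4 of 3 and 24 months. Higher throughout were Ctse (3.32, 1.91, 2.004 and 2.38), Pglyrp1 (2.10, 3.71, 2.30 and 2.15), Emcn (1.82, 2.96, 1.99 and 2.11) and Hlf, a stem cell factor (0.98, 1.86, 0.38 and 1.69), besides Bcl11a, Meis1, Hoxa9 and Tal1. Rescaling moved the median of all genes in 3-month MPP4 from log2 -0.74 to 0.04. Rescaled changes there were 0.54 for Meis1, 0.43 for Hoxa9, 0.70 for Tal1 and 0.74 for Pdzk1ip1, of the stem cell list. Like that of Hlf, these were smaller than that shift, so these genes may not be higher there without rescaling. Lower throughout were the monocyte genes Ccr2 (-2.20, -2.77, -1.06 and -2.23) and Csf1r (-2.87, -0.93, -1.10 and -0.78), Cdkn1a, a p53 target (-0.73, -0.97, -1.54 and -1.89) and Dntt (-2.03, -0.86, -0.40 and -0.27). In 24-month MPP4 rescaling moved the median of all genes from log2 0.43 to 0.06, further than the -0.27 of Dntt. Dntt may thus not be lower there without rescaling. Of fixed lists, 4 of 21 stem cell and quiescence genes and 5 of 41 haematopoietic transcription factors were among the shared higher genes, 73 of 10532 in all. Among the shared lower, 102 of 10532, were 7 of 25 neutrophil and monocyte primed genes and 5 of 19 p53 genes. So were 4 of 18 immediate early and heat shock genes and 3 of 14 macrophage genes. Of the transcription factors 2 were shared lower, and of the macrophage genes 1 was shared higher.

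In libraries labelled KOiMOS 123 of these genes were called, 22 of the higher and 20 of the lower were not, and 10 of the lower were not tested. Of the called genes higher in WTiMOS, 36 went the same way there and 15 the opposite (70.6% of 51), and of those lower 35 and 37 (48.6% of 72). Ctse (4.04) and Pglyrp1 (2.12) rose there as well, Cdkn1a fell (-1.01), and Emcn (0.07) and Ccr2 (0.20) moved little, while Hlf (-0.54) and Flt3 (-0.71) were lower. Flt3 was higher in all 4 WTiMOS tables after rescaling (0.62, 0.29, 0.28 and 0.37). Its direction in 3-month MPP4 depended on the scaling. Without rescaling it was called lower there (log2 -0.63, adjusted p = 1.72e-06). With GC content and length removed it did not pass (log2 0.18, adjusted p = 0.0910). Rescaling turned the direction of 913 called genes between T2 and T1 cells of 3-month MPP4. How many shared higher genes were among them was not counted. The same change in the KOiMOS table is excluded as a general rule for the lower genes by that 48.6%, and the 70.6% left it open for the higher genes. The 175 genes were more than the 13.9 that independent lists would give. All 4 lists came from 1 fit with a spread per gene shared over the tables. They were thus not independent, and the excess alone decides nothing on its source.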
